A study of Homo sapiens with 40 samples.

How the data were processed

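The series holds 40 ChIP-on-chip arrays of acute myeloid leukaemia cells. In ChIP-on-chip, chromatin is precipitated with an antibody (IP), and the recovered DNA is hybridised on a microarray together with total input DNA. The antibodies were against H3K4me3, a histone mark of active promoters, H3K27me3, the mark of Polycomb repression, and EZH2, the enzyme that writes H3K27me3. Cells came from 6 established leukaemia lines and from 7 patient samples, each labelled by whether CDKN2B, the gene of the cell cycle inhibitor p15, carried DNA methylation.

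Per the labels' protocols, lines were fixed with 0.8% formaldehyde for 6 min and sonicated in 15 cycles of 20 s, whereas patient cells were fixed with 1% formaldehyde for 10 min and sonicated in 8 cycles. Fragments were 200 to 600 bp long, and the DNA was amplified over the whole genome before labelling. Input carried Cy3 and the IP carried Cy5 on every array. Because fixation and sonication differed, lines and patient samples were tested apart.

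The authors scanned the arrays and extracted them with Agilent Feature Extraction 9.5.1.1, 9.5.3.1 or 10.1.1.1, per the file headers. The deposited scanner files give, per the file headers, an intensity for each probe and channel after background subtraction and dye normalization, the spot's median intensity and its local background, and a log10 ratio of the processed red over green signals. The authors also deposited a value table of log2 ratios whose construction is not given in the sources used here. Compared with the scanner files, 22 of its columns followed the processed signals (r 0.999 to 1.00, SD of the differences 0.024 to 0.050) and 18 followed the background-subtracted medians without dye normalization (r from 0.999, SD of the differences 0.013 to 0.044). Its columns were not centred: their medians ran from -0.86 to 0.84. Those 18 columns correlated with the processed ratios at only 0.836 to 0.994, so the table served as an alternative and not as the main source.

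There were 2 array designs, with 42808 probes (17 arrays) and 15167 probes (23 arrays), of which 14537 probes were shared. Of all probes, 5792 were custom probes, most of them tiled densely over 9p21. Coordinates are those of hg18 (NCBI36), as in the file headers. Gene names and transcription starts came from the probe annotation in the files: 36 accessions had a start, 35 of these were named through the RefSeq table, and 33 were used. A total of 251 satellite probes and 3 shared probes with conflicting coordinates were left out of the fits.

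From the processed intensities log2(Cy5/Cy3), the IP over input, was computed, control spots were removed, spots marked as outliers were treated as missing (0 to 496 per array) and saturated spots were kept. Each array was centred on its median, with no loess or quantile step, since many probes carry signal. The feature tested was the non-overlapping 1000 bp window with at least 3 probes, valued at the mean of its probes. This gave 3174 windows on the larger design, 808 on the smaller and 782 where probes had to be shared. Promoter values are means over the probes within 1000 bp of a transcription start. A window counted as enriched at a centred log2 ratio of at least 1, which is 2-fold over the array's median.

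Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all windows of a fit and a threshold of 0.05 on the adjusted p. The comparison of 5-aza-dC+TSA with untreated cells held the line as a paired term, because the labels name KG-1 and AML-193 in both arms. Promoter values of CDKN2B and its neighbours were compared by exact permutation tests, two-sided, in a family of 23 tests. With 4 lines against 2 the smallest p such a test can give is 0.0667, with 3 patient samples against 4 it is 0.0286, and with 2 pairs of lines it is 0.5. The labels name separate lines and patients as replicates, except that KG-1a is a subline of KG-1. Single treated patient arrays were described without a test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

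Before the data were examined, the groups, tests, gene lists, most alternatives and the rule for naming windows were set. The rule took, per comparison, the INK4 locus genes whatever their values, up to 10 windows in each direction past the threshold, where fewer than 10 passed the 10 windows of largest moderated t whose groups did not overlap, and up to 4 members of each gene list. For the single treated arrays it took the 10 largest differences in each direction. Of 9 gene lists, 4 had measured members: the INK4 locus and its neighbours (CDKN2B, CDKN2A, MTAP, DMRTA1), genes often DNA methylated in cancer (SFRP4, SFRP5, RARB, MYOD1), developmental regulators known as Polycomb targets (8 genes on the larger design, HOXD3 and PAX6 on the smaller) and housekeeping genes (ACTB, GAPDH). Among the genes often DNA methylated in cancer, 1987 probes were annotated to RARB, against 209 to SFRP4, 173 to MYOD1 and 140 to SFRP5. The windows of that list therefore lie mostly along 1 gene and are not independent. The lists of cell cycle, myeloid, lymphoid, erythroid and chromatin machinery genes had 0 measured members. The developmental list alone had enough members for limma's camera test, which was run with a preset correlation of 0.01 and with an estimated one.

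The alternatives were normexp background correction (offset 50), loess, centring on the mode, scaling of each array's spread, quantile normalization, the value table, a filter on dim input probes, medians over probes, other window widths, eBayes with trend and robust options, 1 joint fit of all untreated arrays, KG-1 and KG-1a averaged, slide as a block, other promoter widths, the fit without the paired term, and each array left out in turn. Normexp used median spot signals in place of the mean signals set beforehand, with control spots kept in its fit. Chosen after seeing the data were the catalogue probes alone, centring on probes outside chromosome 9, limma over promoters alone, and slide as a random block.

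Arrays lay on 12 slides read on 3 scanners. For H3K4me3 in lines 1 slide held 2 methylated and 2 unmethylated lines, and in the other comparisons no slide held 2 arrays of each group. The 4 treated line arrays lay on 1 slide with no untreated array, so treatment and slide cannot be told apart. For H3K27me3 the treated and untreated arrays of these lines were also read on different scanners. Median input intensity per array was 157 to 454 over a local background of 17.0 to 73.5, and median IP intensity was 160 to 953. The share of probes whose input was well above background was 89.3% to 100% per array, and for the IP 77.8% to 100%. The number of arrays limits the precision.

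The fits were tested on simulated data made from the real windows' means and spreads, with noise drawn independently for each window. Changes of 2 and of 4 were each set in 100 of 3174 windows, or in 40 of 782 or 808. Real data with fewer changed windows, or with noise shared by neighbouring windows, may give lower recovery. The shares recovered are therefore not the sensitivity in the real data. For a change of 2 on the log2 scale, limma recovered 67% of changed windows in the H3K4me3 comparison of lines, 29% for H3K27me3 in lines, 65% for EZH2, 95% for H3K4me3 in patient samples and 80% for H3K27me3 in patient samples. Unchanged windows that passed numbered 0 to 9 per comparison. Recovery was 0% in both treatment comparisons, and for a change of 4 it was 72% for H3K4me3 and 0% for H3K27me3 there. Those fits have 1 residual degree of freedom, and the H3K4me3 fit gave every window the same standard error, 0.44.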

Results

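H3K4me3, H3K27me3 and EZH2 were measured by ChIP-on-chip in leukaemia cells grouped by DNA methylation of CDKN2B. The methylated lines were KG-1 (labelled partly methylated), its subline KG-1a, Kasumi-1 and AML-193, and the unmethylated lines were U-937 and HL-60. All 6 lines had 1 array for each of the 3 antibodies. Both histone marks were also measured in 3 methylated (all labelled partly methylated) and 4 unmethylated patient samples, in KG-1 and AML-193 after the DNA methylation inhibitor 5-aza-dC with the histone deacetylase inhibitor TSA (2 µM and 250 nM in KG-1), and in 1 methylated patient sample after each drug alone. Values are log2 of IP over input, centred on each array's median, so they are relative to the tiled regions, which are mostly around 9p21 on the smaller design.

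Marks differed in how much of the tiled sequence they covered, over 3174 windows for the histone marks in lines and for EZH2 in U-937, and over 808 windows for the other arrays. H3K4me3 was enriched 2-fold in 10.4% to 20.0% of windows in untreated lines and in 5.20% to 11.8% in untreated patient samples. H3K27me3 covered 13.5% to 30.8% in untreated lines and 11.4% to 20.4% in untreated patient samples. EZH2 covered 0% (AML-193) to 6.56% (KG-1) in lines, and 0 windows were enriched in every line of either group. Among H3K27me3 line arrays, U-937 (13.5%) and AML-193 (16.8%) lay lowest.

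**Figure D1:**
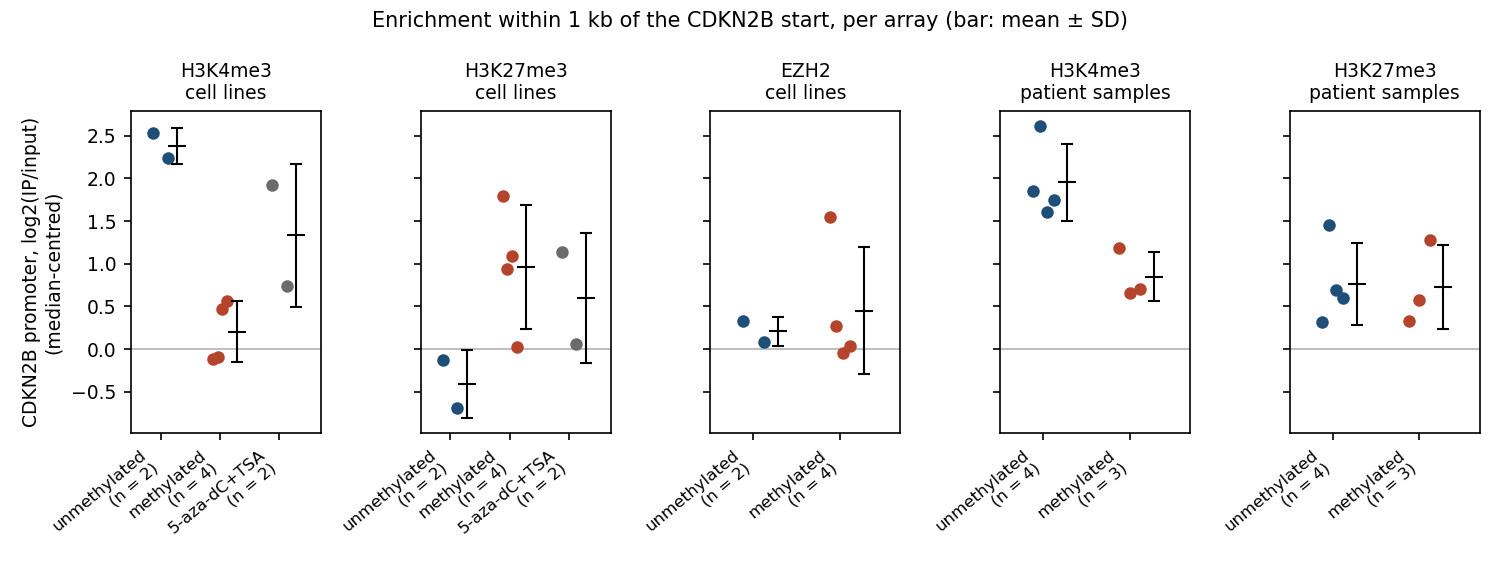
Centred log2(IP/input) over the CDKN2B promoter (within 1000 bp of its start) for each array (dots) by antibody and group, with the mean ± SD beside them. The 4 methylated lines lie at -0.12 to 0.56 for H3K4me3, below the unmethylated lines at 2.53 and 2.23.

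The comparison of lines asked how chromatin at CDKN2B differs where its DNA is methylated. H3K4me3 was lower in the 4 methylated lines at the 5' part of CDKN2B: over 9:21998001 (chromosome 9, 21998001 to 21999000, inside the gene, 109 probes) it was -0.16 ± 0.44 (SD, n = 4) against 3.17 ± 0.18 (SD, n = 2), a difference of -3.33 (SE 0.35, limma adjusted p = 0.0438). Over the promoter (chromosome 9, 21998312 to 22000312, 222 probes) the difference was -2.18, with KG-1 at -0.12, KG-1a at -0.09, Kasumi-1 at 0.47 and AML-193 at 0.56 against U-937 at 2.53 and HL-60 at 2.23. The exact permutation p was 0.0667, the smallest this design allows, and the difference ran from -2.54 to -0.90 over 23 alternatives, the smallest over all probes of the gene. At CDKN2A, the neighbour that encodes p16 and ARF, the promoter differences were 0.39 (exact permutation p = 0.667) and 0.17 (exact permutation p = 0.8), within the spread between lines.

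Among the INK4 locus and its neighbours, 6 of 113 windows had lower H3K4me3 in the methylated lines when adjusted over the list alone, and 1 when adjusted over all windows. Besides CDKN2B, the largest differences in that list were at MTAP, a methionine salvage enzyme (9:21823001, -2.65, adjusted p = 0.369). Of the developmental regulators, HOXD11 was -1.58 at 2:176676001 (adjusted p = 0.286), HOXD3 -0.81, HOXD8 0.78 and PAX6 1.91, and 1 of 45 windows passed when adjusted over the list alone. Of 211 windows at genes often DNA methylated in cancer 0 passed in limma, and 6 had an unadjusted p under 0.05, all lower (RARB -1.19). The RARB promoter differed by -2.10 (0.74 ± 1.70 against 2.84 ± 0.74), with overlapping groups (adjusted p = 0.695 over promoters alone). Of 12 windows in or near housekeeping genes 0 passed (ACTB 1.04, GAPDH 0.67), and their promoters differed by 0.23 and 0.52.

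In all, 2 of 3174 windows passed, both lower in the methylated lines. The other was 7:27210001 (chromosome 7, 27210001 to 27211000, no gene named in the files), at -0.11 ± 0.12 against 2.36 ± 0.31 (adjusted p = 0.0438). At an unadjusted p under 0.05 there were 105 windows, 42 higher and 63 lower. Next by moderated t, among windows whose groups did not overlap, came 12:52761001 (2.58), 9:21997001 in CDKN2B (-3.02) and 12:52762001 (2.10). Each had a limma adjusted p of 0.161, and those on chromosome 12 carry no gene name. The groups did not overlap in 10.7% of windows, against 13.3% by chance. KG-1a is a subline of KG-1, and with these 2 averaged 9:21998001 stood at -3.21 (adjusted p = 0.214) and 0 windows passed. Leaving out any 1 array ended the call at 9:21998001 (adjusted p 0.0720 to 0.226) with the difference at -3.47 to -3.16, and slide as a block gave adjusted p = 0.495 in a range of 0.000225 to 0.495 over 21 alternatives. Within the slide that held 2 lines of each group the promoter difference was -2.21.

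**Figure D2:**
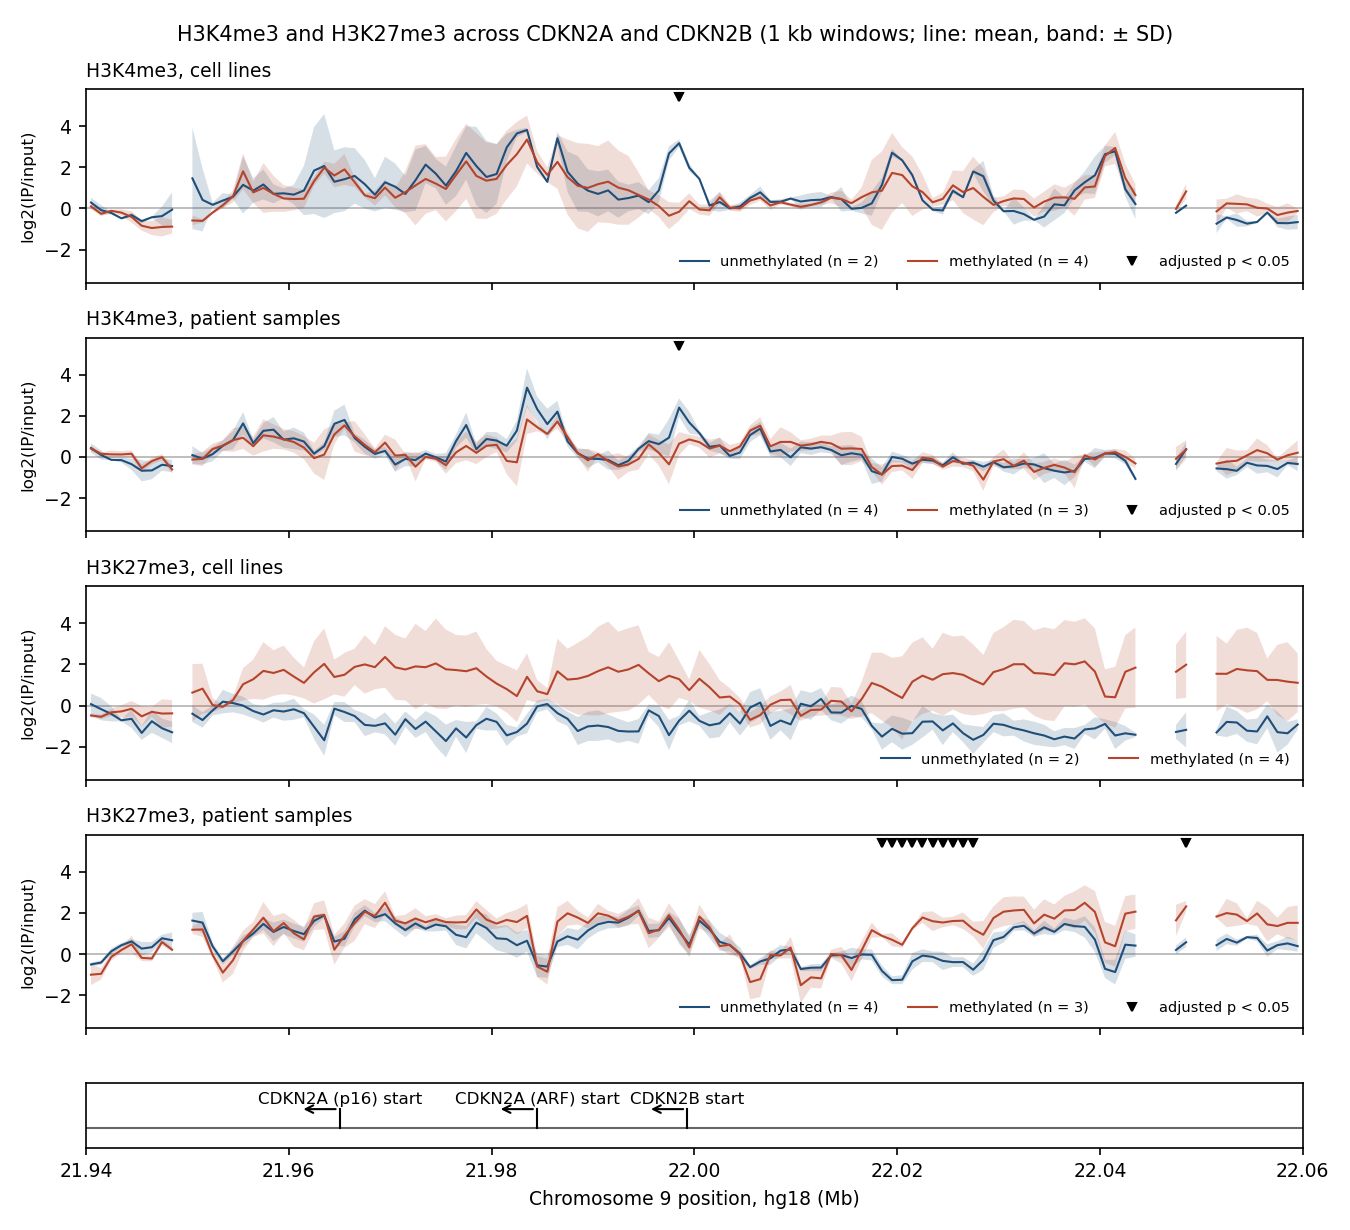
Mean centred log2(IP/input) in 1000 bp windows along chromosome 9 (hg18) in methylated and unmethylated lines and patient samples, with bands of ± SD, transcription starts below and triangles at windows with a limma adjusted p under 0.05. The H3K4me3 peak of the unmethylated groups at the CDKN2B start (3.17 in lines, 2.40 in patient samples at 9:21998001) is lower in the methylated groups, and the 11 marked H3K27me3 windows of patient samples lie upstream of CDKN2B.

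For H3K27me3 the methylated lines had higher values along CDKN2A and CDKN2B, though 0 of 3174 windows passed in limma (463 at an unadjusted p under 0.05, of which 163 higher and 300 lower; smallest adjusted p 0.340). At CDKN2A the differences reached 3.71 (9:21963001, 2.03 ± 1.72 against -1.69 ± 0.76, n = 4 and 2) and 2.85 (9:21968001), and inside CDKN2B 3.23 (9:21994001). AML-193 lay far below the other methylated lines at 9:21963001 (-0.52) and 9:21994001 (-0.90), so those differences rest mainly on the other lines. In the INK4 list 43 of 113 windows were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The CDKN2B promoter differed by 1.37 (0.96 ± 0.73 against -0.41 ± 0.40; exact permutation p = 0.133) and the p16 promoter by 1.71 (exact permutation p = 0.133). Per line the CDKN2B promoter stood at 1.79 in KG-1, 0.94 in KG-1a, 1.09 in Kasumi-1 and 0.02 in AML-193, against -0.12 in U-937 and -0.69 in HL-60.

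At genes often DNA methylated in cancer 48 of 211 windows were lower and 0 higher at an unadjusted p under 0.05, beside 300 lower of all 3174, and 0 passed when adjusted over the list alone. The genes did not all share that direction (RARB -2.10 at 3:25468001, SFRP4 0.46 at 7:37921001). Centring on the mode moves every H3K27me3 difference between lines by 0.90, which turns the list's median from -0.68 to above 0. HOXD13 stood at 1.89, PAX6 at 0.85, GAPDH at -0.29 and ACTB at -0.22 (the last 3 change sign under other settings), and none of these passed. The AML-193 array had weaker H3K27me3 enrichment than the other 3 methylated lines. Its median gap to them was -1.32 over 490 windows outside chromosome 9 that were picked as enriched in those 3. The same measure was 0.09 for KG-1, 0.10 for KG-1a and 0.58 for Kasumi-1. Without AML-193 60 windows passed (57 higher, 3 lower). U-937, an unmethylated line, had even fewer enriched windows (13.5%, against 16.8% in AML-193), so a weak array lay on each side of this comparison. With slide as a block 30 windows passed, and within 1 slide (2 against 1) the CDKN2B promoter difference was 1.25.

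EZH2 at the CDKN2B promoter overlapped between the groups, with a difference of 0.24 (0.45 ± 0.74, n = 4, against 0.21 ± 0.17, n = 2; exact permutation p = 0.933). KG-1 was highest at 1.55, the other methylated lines were at 0.27, -0.05 and 0.04, and without KG-1 the difference was -0.12. Inside the gene, at 9:21993001, the groups did not overlap (0.78 ± 0.69 against -0.47 ± 0.56; difference 1.25, unadjusted p = 0.0228, limma adjusted p = 0.711). At the p16 promoter the difference was 0.97 (exact permutation p = 0.333). In limma 0 of 782 windows passed, with 41 at an unadjusted p under 0.05 (smallest adjusted p 0.711). The largest moderated t values belonged to PAX6, an eye and brain regulator (11:31775001, -1.75), and CDKN2A (9:21973001, 1.33); 1 of 24 developmental windows passed when adjusted over the list alone. In the INK4 list 11 of 112 windows were higher and 3 lower at an unadjusted p under 0.05, and of the genes often DNA methylated in cancer 13 of 211 were lower (RARB -1.20, SFRP5 -1.13). With the centre outside chromosome 9 every EZH2 difference moves by 0.45, which takes up nearly all of that list's median of -0.47. Within the slide that held 3 methylated lines and 1 unmethylated line the promoter difference was -0.02.

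The patient samples were compared in the same way. H3K4me3 was lower in the 3 methylated samples at CDKN2B, over the same window as in lines: 9:21998001 had 0.65 ± 0.56 (SD, n = 3) against 2.40 ± 0.45 (SD, n = 4), a difference of -1.75 (SE 0.33, limma adjusted p = 0.0493). The promoter (223 probes) stood at 0.85 ± 0.29 against 1.95 ± 0.45, a difference of -1.10 (exact permutation p = 0.0286, the smallest of 35 arrangements; 0.438 after adjustment over the family). Differences at the ARF part of CDKN2A were -1.55 (9:21983001) and -1.54 (9:21982001), each with adjusted p = 0.560, and the ARF promoter differed by -0.92 (exact permutation p = 0.0857). The p16 and MTAP promoters differed by -0.38 and -0.26.

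Of the gene lists, the INK4 list had 1 of 127 windows and the developmental list 1 of 24 (smallest adjusted p 0.0312; its largest moderated t was at PAX6 11:31787001, -1.25) lower when adjusted over the list alone. Genes often DNA methylated in cancer (RARB 0.63, MYOD1 0.68) and housekeeping genes (ACTB -0.87, GAPDH -0.46) had 0 windows past the threshold. Over all 808 windows 1 passed and 35 had an unadjusted p under 0.05, and the groups did not overlap in 4.83% of windows, against 5.71% by chance. The window's call ended without methylated replicate 2 (-1.45, adjusted p = 0.697) or 3 (0.430), or without unmethylated replicate 1 (0.145) or 4 (0.0588), in a range of 0.00338 to 0.998 over 21 alternatives. With slide as a block the difference was -0.97 (adjusted p = 0.997), and within the slide that held 2 methylated samples and 1 unmethylated sample the promoter difference was -0.66.

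H3K27me3 at the CDKN2B promoter itself did not differ beyond the spread between patient samples (0.73 ± 0.49, n = 3, against 0.77 ± 0.48, n = 4; difference -0.04, exact permutation p = 0.886). That promoter difference depends on the centring, at -1.08 with the mode as centre and 0.98 with the centre outside chromosome 9. Upstream of the gene, 11 windows had higher H3K27me3 in the methylated samples, 18.7 to 49.7 kb from the CDKN2B start. Of these, 10 were contiguous (chromosome 9, 22018001 to 22028000) and the other was 9:22048001. They carry no gene symbol here, but of the 10 named windows the files place 4 inside and 5 downstream of a transcript record. Differences were 1.61 to 2.01, as at 9:22025001 with 1.61 ± 0.21 against -0.39 ± 0.23 (2.00, SE 0.35, limma adjusted p = 0.0206), and adjusted p ranged from 0.0206 to 0.0457.

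At CDKN2A, 9:21983001 was 1.20 higher (adjusted p = 0.0896), while MTAP (9:21791001, -1.67) and DMRTA1 (9:22444001, -1.74) stood lower, both with adjusted p = 0.0604. Of the genes often DNA methylated in cancer, 54 of 211 windows were lower when adjusted over the list alone and 0 over all windows. The list median was -0.96 and the largest moderated t was at RARB (3:25494001, -1.64), along which most of these windows lie. The promoters differed by -0.41 (RARB), -0.87 (SFRP4), -0.72 (SFRP5) and -0.63 (MYOD1), with limma adjusted p of 0.340 to 0.594 over promoters alone. Values at ACTB (-1.13) and GAPDH (-1.19) were lower too, but neither passed the threshold. The size of these lower values depends on the centring. Probes outside chromosome 9 as the centre move every difference by 1.01, so that the list median rises above 0. The windows named here at MTAP, DMRTA1, RARB, ACTB and GAPDH stay below 0 under that shift. The mode moves every difference by -1.04, which leaves the 11 windows upstream of CDKN2B at 0.56 to 0.97. The groups did not overlap in 23.8% of windows, against 5.71% by chance, and 262 had an unadjusted p under 0.05 (81 higher, 181 lower).

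The count of 11 was 0 with normexp, with the mode as centre, in 1 joint fit and with slide as a block, and 0 without methylated replicate 1 or without any 1 of the 4 unmethylated replicates, although with any 1 array left out the differences at the 10 named windows stayed at 1.56 to 2.24 (adjusted p up to 0.150). It rose to 422 (94 higher, 328 lower) without methylated replicate 3 and to 173, all higher, with the centre outside chromosome 9, and within the slide that held 1 sample of each group the mean difference of the 11 windows was 1.70.

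Whether the methylation effect differed between lines and patient samples was tested directly on the 782 shared windows. For H3K4me3 0 windows passed in limma (40 at an unadjusted p under 0.05), and the CDKN2B promoter effects of -2.18 in lines and -1.09 in patient samples differed by -1.09 (permutation p = 0.371 over 525 arrangements). For H3K27me3 0 windows passed (68 at an unadjusted p under 0.05), and the effects of 0.76 and -0.04 differed by 0.80 (permutation p = 0.185). The effect in lines is 0.76 here and 1.37 above, because this fit uses only the shared probes, centred on their own median. All methylated patient samples but only 1 of the 4 methylated lines, KG-1, are labelled partly methylated, so the degree of methylation differs between the origins too. Without AML-193 94 windows passed for H3K27me3, and with the mode as centre the difference at CDKN2B was 3.32 (permutation p = 0.0229).

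Treatment with 5-aza-dC+TSA was compared with the untreated state of the same lines. H3K4me3 over the CDKN2B promoter was 1.33 ± 0.84 after treatment against 0.22 ± 0.48 before (n = 2 each; difference 1.11, exact permutation p = 0.5, the smallest of 4 arrangements; 0.37 to 1.70 over 18 alternatives). The difference was 2.04 in KG-1 and 0.18 in AML-193, and at the p16 promoter 0.93 and 0.34. Windows enriched for H3K4me3 went from 11.5% to 21.6% over the whole KG-1 array and from 12.9% to 14.1% in AML-193, so the difference in KG-1 was not confined to CDKN2B. In limma 9:21998001 at CDKN2B stood at 1.40 (adjusted p = 0.151), RARB at 1.44 (3:25444001), SFRP5 at 1.39 and PAX6 at 1.32. A single window of 3174 passed, at DMRTA1, a transcription factor gene near the INK4 locus (9:22439001, -0.34 ± 0.54 against 1.56 ± 3.18; difference -1.90, adjusted p = 0.0429). Without the paired term the same window had adjusted p = 0.777, and the difference was then 0.35 without the untreated KG-1 array and -4.15 without the untreated AML-193 array, so the call rests on the untreated level of 1 line.

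Of the developmental regulators 15 of 45 windows were higher and 1 lower at an unadjusted p under 0.05, with a median of 0.60 and 0 passing when adjusted over the list alone. Camera with the preset correlation gave adjusted p = 3.84e-10 for this list, and adjusted p = 0.854 with an estimated correlation (the other 3 fits with enough members gave 0.109 to 0.311 and 0.854). In the INK4 list 7 of 113 windows passed when adjusted over the list alone, with 9 higher and 14 lower at an unadjusted p under 0.05 (CDKN2A 9:21972001, -1.57). Genes often DNA methylated in cancer (MYOD1 1.11, SFRP4 -1.07) and housekeeping genes (ACTB -0.90, GAPDH -0.82) had 0 windows past the threshold adjusted over the list alone.

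H3K27me3 after treatment gave 0 of 3174 windows in limma, with 27 at an unadjusted p under 0.05 (smallest adjusted p 1.00). The CDKN2B promoter stood at 0.60 ± 0.76 after and 0.91 ± 1.25 before treatment (difference -0.31, exact permutation p = 1.00), with -0.66 in KG-1 and 0.04 in AML-193. The 4 lists had 0 windows past the threshold adjusted over the list alone (RARB 1.16, HOXD13 -0.59, CDKN2A -0.74). Simulated changes of 4 on the log2 scale were recovered in 0% of windows for this fit, so changes of that size were not detectable. Treated arrays shared 1 slide that held no untreated array, and for H3K27me3 they were read on another scanner than the untreated arrays. Treatment, slide and scanner therefore cannot be told apart for this mark.

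In the methylated patient sample treated with single drugs there was 1 array per condition and no replicate check. Treated arrays lay on other slides and were read on another scanner than the untreated arrays of this sample. Drug, slide and scanner therefore cannot be told apart in these differences. After 5-aza-dC (2 µM) the H3K4me3 differences were largest at ACTB (7:5537001, 1.93), GAPDH (12:6514001, 1.93), PAX6 (11:31782001, 1.85), SFRP4 (7:37922001, 1.81) and CDKN2A (9:21984001, 1.73). The CDKN2B promoter differed by 0.41 and the ARF promoter by 1.47. Median differences were 0.64 over the developmental list, 0.53 over housekeeping genes, 0.15 over genes often DNA methylated in cancer and -0.10 over the INK4 list, beside -0.05 over all windows. After TSA (250 nM) PAX6 stood 1.61 higher, MXD1, a MYC antagonist, 1.29 higher and MTAP -1.29 lower, with CDKN2B at 0.02.

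For H3K27me3 in the same sample, 5-aza-dC went with higher values at MYOD1, a muscle regulator (11:17699001, 1.77), and SFRP5, a WNT inhibitor (10:99520001, 1.30), and with lower values at MXD1 (2:70011001, -2.11). TSA went with a difference of -1.19 at 9:22039001 and 1.08 at RARB (3:25444001). The CDKN2B promoter differed by 0.17 after 5-aza-dC and by -0.07 after TSA.

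The relation of EZH2 to H3K27me3 was described across windows within each line, which are not independent. In KG-1, KG-1a, Kasumi-1 and HL-60 the Pearson correlation was 0.62, 0.55, 0.58 and 0.45, and in KG-1 52 of 54 windows with EZH2 were also enriched for H3K27me3 (8.63 if independent). These 4 lines and AML-193, at -0.05 with 0 windows with EZH2, were compared over 782 shared windows. U-937, whose arrays were both of the larger design, was compared over 3174 windows and stood at 0.03, with 0 of 32 windows with EZH2 also enriched for H3K27me3. Between H3K4me3 and H3K27me3 the mean correlation was 0.14 in lines and 0.14 in patient samples over all windows. Windows enriched for both marks numbered 350 in HL-60 (196 if independent), 223 in Kasumi-1 (135), 142 in KG-1 (101) and 129 in KG-1a (124), but 59 in AML-193 (68.9) and 9 in U-937 (44.8).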

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

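The tests of explanations in this part concern patterns found in these data, and most were chosen after the result was seen. Recorded as set earlier were the regrouping of the 7 patient samples and the tests of how strongly H3K27me3 was enriched. The enrichment test in patient samples, however, used the centre outside chromosome 9, which was chosen after seeing the data.

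A total of 10 of 128 groups of 4 samples (7.81%) had 1 sample far from the other 3, where chance gives about 5%. Of these, 6 were the H3K27me3 array of AML-193 (methylated replicate 4): it was lowest at 9:21963001 (-0.52), 9:21970001 (-0.50), 9:21967001 (-0.11), 9:21994001 (-0.90) and 9:21992001 (-1.26), in CDKN2A and CDKN2B, and highest at 3:25468001 in RARB (0.17). These windows neighbour each other and are not independent. KG-1a (methylated replicate 2) was highest for EZH2 at the ARF promoter (1.37). Among unmethylated patient samples, replicate 1 was lowest for H3K4me3 at GAPDH (12:6515001, 3.19) and for H3K27me3 at CDKN2A (9:21983001, -0.13), and replicate 4 was lowest for H3K27me3 at 9:22026001 (-0.75).

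KG-1 and AML-193 moved in opposite directions with 5-aza-dC+TSA in 3 promoter values, each from 1 array per line and condition, and the differences between lines were not tested. H3K4me3 at the ARF promoter differed by 0.77 in KG-1 and by -0.81 in AML-193. H3K27me3 differed by -0.66 and 0.040 at the CDKN2B promoter, and by -0.80 and 0.10 at the ARF promoter. For H3K27me3 the AML-193 differences are near 0 and set against its weakly enriched untreated array (16.8% of windows, 24.6% when treated), and the labels give a dose for KG-1 only, so the lines are not well matched.

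The lower H3K4me3 at the CDKN2B promoter of methylated lines and patient samples was weighed against technical causes. A loss of gene copies shared by the methylated lines was not seen, as their input over the promoter differed by -0.16 (exact permutation p = 0.667). Per line the input was 0.31 in KG-1, 0.12 in KG-1a, -0.10 in AML-193 and -0.53 in Kasumi-1, against 0.43 in U-937 and -0.21 in HL-60. A group mean cannot exclude a loss in 1 line, such as Kasumi-1. Weak arrays were excluded as the whole cause in lines. There 8 other promoters had a median difference of 0.35, and only 2 of them were lower (the lowest, RARB, by -2.10). Slide was excluded in lines (-2.21 within 1 slide) but could not be told apart in patient samples (-0.66 within 1 slide of 2 against 1). In patient samples 9 other promoters, all lower, had a median difference of -0.32 (the lowest -0.92, at ARF), too small at the median to be the whole of -1.10. Only 1 of 35 ways to group the 7 samples, the real one, gave any window past the threshold, and it gave 1. No lower share than 1 of 35 is possible, so a chance split is made less likely but not excluded. DNA methylation as the biological explanation stays a hypothesis in lines, and in patient samples it was not separated from slide.

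The block of 11 windows with higher H3K27me3 upstream of CDKN2B in methylated patient samples was weighed in the same way. Its direction held under every centre, but the size did not, so centring stays open: the mean difference was 1.83, 2.84 with the centre outside chromosome 9, and 0.79 with the mode as centre, where 0 windows passed. In the regrouping, 1 of 35 groupings, the real one, gave 11 windows and no other more than 4. That is the lowest share 35 groupings can give, so a chance split is made less likely but not excluded. Slide could not be told apart (1.70 within the slide that held 1 sample of each group), nor could stronger enrichment of the methylated samples' arrays. For the latter, 35 windows outside chromosome 9 had a median difference of 0.86 against 2.84 under that centring. These windows were picked as enriched in all unmethylated samples, which tends to lower their difference. DNA methylation of CDKN2B may be the biological cause, but the causes that stay open were not separated from it.

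The AML-193 H3K27me3 array, which stood apart from the other methylated lines, was weighed last. Weak enrichment of the array was not excluded. Its median gap to the other 3 lines was -1.32 over 490 windows outside chromosome 9, lower in 450 of them, and -1.25 at the CDKN2B promoter. These windows were picked as enriched in the other 3 lines, which tends to put the remaining line lower. The same measure was, however, 0.09 for KG-1, 0.10 for KG-1a and 0.58 for Kasumi-1. For slide, the correlation with Kasumi-1 on its own slide was set against that with U-937 on another. The first minus the second was 0.16 over all 3174 windows and -0.69 over the 782 windows shared by the designs. The shared windows are mostly around 9p21, where the pattern itself was seen, so they cannot decide on slide. In both sets the best match was HL-60, an unmethylated line on the same slide (0.759 over all and 0.794 over shared windows). Slide therefore stays open. DNA of another line was excluded for the input alone. This input correlated at 0.875 with the AML-193 H3K4me3 array and at most at 0.164 with another line. The IP is a separate DNA sample on the array, so a mix-up of the IP was not tested. A lower level of H3K27me3 in this line is the biological explanation. The treated AML-193 array lay on another slide and had 24.6% of windows enriched. Its CDKN2B promoter stood at 0.06, against 0.02 untreated and 1.14 in treated KG-1. The p16 promoter stood at 0.28 treated and 0.30 untreated, and the ARF promoter at 0.47 and 0.37. As 1 array of treated cells it cannot separate these causes. A repeat of the untreated array would be needed to tell a lower level from weak enrichment, slide or a mixed-up IP.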

How the results depend on the processing

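Most alternatives were set before the data were examined; the catalogue probes alone, centring outside chromosome 9, limma over promoters alone and slide as a random block were chosen after the result was seen. Of 449 values under alternatives for the 44 results that answer a comparison, 308 stayed as they were; for the 155 named windows it was 2650 of 2955. Beyond what a setting's own construction shows, the cause was not tested. A left-out array that leaves 1 array in a group assumes that this array varies like the others. Slide as a random block could not be fitted for the treatment comparisons.

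For H3K4me3 in lines the count of 2 windows was 0 with loess, the mode as centre, scaled spread, quantile normalization, catalogue probes, the centre outside chromosome 9, windows of 2000 bp, trend and robust options, KG-1 and KG-1a averaged, slide as a block and within 1 slide. It was 1 with windows of 500 bp, 102 with single probes (more features tested), 5 in 1 joint fit and 0 to 3 with 1 array left out. At 9:21998001 the direction was kept in 21 of 21 alternatives, with -3.79 to -2.63 and 5 past the threshold, and at 7:27210001 in 20 of 20. The CDKN2B promoter difference of -2.18 kept its direction in 23 of 23, at -2.54 to -0.90 (smallest over all probes of the gene), and at -2.32 to -2.03 with 1 array left out.

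For H3K27me3 in lines the count of 0 became 254 in 1 joint fit (55 higher, 199 lower), 30 with slide as a block (all higher), and 0 to 60 with 1 array left out. With the mode as centre 6 windows changed sign: SFRP5 10:99517001 0.23, MYOD1 11:17699001 0.43, HOXD1 2:176771001 0.024, GAPDH 12:6517001 0.61, ACTB 7:5534001 0.68 and MTAP 9:21821001 0.38. The shift of 0.90 that this centre gives every window explains these changes. With the centre outside chromosome 9 GAPDH was 0.0094 and ACTB 0.079. SFRP4 7:37921001 was -0.20 in 1 joint fit. Within the slide of 2 against 1 SFRP4 was -0.040, PAX6 11:31782001 -0.076, HOXD8 2:176700001 -0.85, GAPDH 0.12 and ACTB 0.40. With 1 array left out MYOD1 ranged from -1.08 to 0.13, GAPDH from -0.61 to 0.034, ACTB from -0.66 to 0.23 and HOXD8 from -0.20 to 2.11. The CDKN2B promoter kept its direction in 23 of 23 alternatives (0.63 to 2.47).

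For EZH2 the count of 0 was 1 with quantile normalization. The CDKN2B promoter difference of 0.24 became -0.048 with quantile normalization, -0.041 over 500 bp either side, -0.0026 with slide as a block and -0.025 within 1 slide, and -0.12 to 0.41 with 1 array left out. It was highest, at 0.69, with the centre outside chromosome 9, which moves every EZH2 difference by 0.45.

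For H3K4me3 in patient samples the count of 1 was 0 with normexp, the mode as centre, scaled spread, quantile normalization, the value table, the filter on dim input, the centre outside chromosome 9, windows of 500 or 2000 bp, single probes, trend and robust options, 1 joint fit, slide as a block and within 1 slide, and 0 to 1 with 1 array left out. The CDKN2B promoter difference of -1.10 was weaker but of the same direction with normexp (-0.41), medians over probes (-1.03), 500 bp either side (-0.76), all probes of the gene (-0.50), slide as a block (-0.66) and within 1 slide (-0.66), and -1.27 to -0.89 with 1 array left out. GAPDH 12:6515001 was 0.15 with normexp and 0.26 with quantile normalization, and HOXD3 2:176744001 was -0.47 to 0.32 with 1 array left out.

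For H3K27me3 in patient samples the count of 11 was 0 with normexp, the mode as centre, 1 joint fit and slide as a block. It was 67 with loess (13 higher, 54 lower), 47 with quantile normalization (19 higher, 28 lower), 173 with the centre outside chromosome 9 (all higher, by its shift of 1.01), 20 with windows of 500 bp, 6 with 2000 bp, 1025 with single probes (more features tested), 204 with trend and robust options (62 higher, 142 lower) and 0 to 422 with 1 array left out. The 10 of these 11 windows that were named kept their direction in all 20 alternatives each. The CDKN2B promoter difference of -0.04 became 0.020 with normexp, 0.23 with catalogue probes, 0.98 with the centre outside chromosome 9, 0.45 with medians, 0.075 over 2000 bp either side, 0.090 over all probes of the gene and 0.59 with slide as a block or within 1 slide, and -0.31 to 0.19 with 1 array left out. It was -1.08 with the mode as centre, so over all alternatives it ran from -1.08 to 0.98. With the centre outside chromosome 9 CDKN2B 9:22008001 was 0.78, MYOD1 11:17696001 0.25, PAX6 11:31783001 0.40 and HOXD3 2:176744001 0.81. With slide as a block PAX6 was 0.50, HOXD3 0.77, ACTB 7:5534001 0.16 and GAPDH 12:6517001 0.36. HOXD3 was 0.11 with medians and -0.43 to 0.17 with 1 array left out.

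For the difference between lines and patient samples, the H3K27me3 count of 0 was 18 with scaled spread and 0 to 94 with 1 array left out, and the H3K4me3 count was 0 to 1. The CDKN2B difference of 0.80 for H3K27me3 was 3.32 with the mode as centre.

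For treated lines and H3K4me3 the count of 1 was 0 with normexp, the mode as centre, scaled spread, quantile normalization, the filter on dim input, medians over probes, windows of 2000 bp, no paired term and each array left out. It was 54 with loess (14 higher, 40 lower), 6 with windows of 500 bp, 175 with single probes (46 higher, 129 lower) and 9 with trend and robust options (all lower). With the value table it was 502 (261 higher, 241 lower), where untreated columns lack the dye normalization that treated columns have. With 1 array left out, which also drops the paired term, DMRTA1 9:22439001 ranged from -4.15 to 0.35, CDKN2A 9:21972001 from -3.51 to 0.38, 9:21992001 from -2.71 to 0.67, RARB 3:25444001 from -0.18 to 3.07 and MTAP 9:21804001 from -2.23 to 0.56. The CDKN2B promoter difference of 1.11 ran from 0.37 (all probes of the gene) to 1.70, and from 0.52 to 1.70 with 1 array left out. Camera on the developmental list went from adjusted p = 3.84e-10 to 0.854 with an estimated correlation.

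For treated lines and H3K27me3 the count of 0 was 1 with trend and robust options. The CDKN2B promoter difference of -0.31 was 0.17 with loess and -1.19 to 0.58 with 1 array left out. RARB 3:25614001 was 0.042 with normexp, ACTB 7:5536001 0.049 with loess, and GAPDH 12:6513001 0.057 with loess and 0.095 with the mode as centre. With 1 array left out these 3 ranged from -1.36 to 0.39, -0.93 to 0.24 and -0.81 to 0.44. MTAP 9:21842001 ranged from -2.13 to 0.20, CDKN2A 9:21969001 from -2.16 to 0.67, CDKN2B 9:21994001 from -2.51 to 1.42, SFRP4 7:37912001 from -1.09 to 0.13, PAX6 11:31781001 from -1.67 to 0.52, HOXD8 2:176700001 from -1.49 to 0.64 and HOXD1 2:176771001 from -0.82 to 0.16.

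Over windows enriched for either mark the mean correlation of H3K4me3 with H3K27me3 was -0.54 in lines and -0.57 in patient samples, and with EZH2 it was -0.19; keeping such windows pushes the correlation below 0 by itself, so these values say nothing about the marks. Windows enriched in every sample of a group depend on the level asked for. At 1.5-fold they were 273 (H3K4me3) and 471 (H3K27me3) in methylated lines, 502 for H3K27me3 in unmethylated lines, 551 for H3K4me3 in treated lines, 9 and 1 for EZH2 in unmethylated and methylated lines, 56 and 96 for the 2 marks in unmethylated patient samples, and 76 and 105 for H3K4me3 after TSA and after 5-aza-dC in the patient sample. At 3-fold they were 152 and 73 in unmethylated lines, 96 and 131 in methylated lines, 127 and 268 in treated lines, 20 and 19 in unmethylated and 10 and 16 in methylated patient samples, 26 and 77 after TSA and 42 and 69 after 5-aza-dC. A replicate block across the antibodies moved the count of windows that differ between H3K4me3 and H3K27me3 from 1128 to 1188 in lines and from 440 to 455 in patient samples, by less than 1.5 times, and no call of the report rests on it. Signal over background limits the weakest arrays, where 77.8% of IP probes lay well above background.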

Other observations

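None of the comparisons in this part was a test, and the regions to describe were chosen after the result was seen.

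Satellite probes (251, chromosome repeats, left out of the fits) had low H3K27me3 in untreated patient samples, with centred log2 ratios from -3.87 to -1.42, and higher H3K4me3, from 0.20 to 1.20. In untreated lines their H3K27me3 ran from -1.72 to 0.00. Their H3K4me3 was 0.32 before and -0.69 after 5-aza-dC+TSA in KG-1, and 0.16 and -0.21 in AML-193.

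Over windows, H3K4me3 of KG-1 and its subline KG-1a correlated at 0.948 and H3K27me3 at 0.815. H3K27me3 of AML-193 correlated at 0.759 with HL-60 and 0.607 with Kasumi-1, both on its slide, and at 0.583 with KG-1, 0.535 with KG-1a and 0.449 with U-937 on other slides. By input signal, 5 of 6 lines' H3K27me3 arrays matched the H3K4me3 array of their own line best. The other was KG-1a, at 0.869 with its own line and 0.917 with KG-1, from which it derives; both lines are in the methylated group, so the comparison of groups does not turn on it.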
